A study of Homo sapiens with 30 samples.

How the data were processed

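Total RNA of 30 samples was sequenced from KAPA RNA HyperPrep libraries of HCT116, HL60, MCF7 and HepG2, 14 without siRNA and 16 with an siRNA in HCT116. The submitters' processing notes name TopHat2 2.1.0, HISAT and the hg19 genome, and how reads were counted, how reads that map to several repeats were handled and how strand was treated are not stated. Only the deposited processed tables were used. Coordinates are those of the tables on hg19.

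The siRNA LTR tables hold a score per library which, per the file headers, is the read number in 50 M reads (M, 1000 × 1000), rounded by the authors to whole numbers. The cell-line table holds a signal which, per the file headers, is the read number in 50 M reads, and the authors divided each column by 1 factor without rounding. RPKM values for LTR copies and genes, reads per kilobase of feature and per M reads, were computed by the authors. The fold values in the LTR tables are the authors' ratios of RPKM, given only where a scaled count reached 20, and the gene table holds the authors' log2 ratios to PBS siNon-target. CpG density is deposited as a ratio of CpG dinucleotides to length. Divergence of a subfamily is deposited as a fraction. The rates of the age table are the authors' score of upregulated copies per 1000 elements. The gene table's counts were deposited as whole counts at each library's own depth, although its header names 50 M reads, as the ratio of counts to RPKM showed.

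Whole reads were recovered from RPKM times copy width, which fell on multiples of 1 step per library, and 91.1% to 100% of low values lay within 0.1 of a whole read. Recovered reads served for counting intervals and for edgeR. The cell-line columns with 5-aza-CdR implied 23.6 M reads in HepG2 and 48.8 to 55.8 M in the other lines, so HepG2 copies carry wider intervals. The RPKM of the cell lines used larger denominators, 74.4, 60.7, 64.2 and 74.9 M with PBS and 68.0, 59.2, 63.5 and 30.0 M with 5-aza-CdR in HCT116, HL60, MCF7 and HepG2. Depths of the siRNA libraries differed between the LTR and gene tables, as in PBS siSUV39H2 (50.7 and 77.2 M).

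For LTRs, the log2 ratio of RPKM plus 0.1 was taken for each copy with a mean RPKM of at least 0.1 over its table, and copies at 2-fold or more were counted. In the cell-line table, 6449 of 7695 copies (5301 LTRs and 2394 internal parts in 470 subfamilies) passed. For the siRNAs, 791 copies of 219 subfamilies with PBS and 1032 of 1033 copies of 227 subfamilies with 5-aza-CdR passed. The cell-line table lists copies whose highest scaled count is at least 20.1, and the siRNA tables list copies with a fold of at least 2 and a scaled count of at least 20. Chance counts came from simulated Poisson reads. Each of 11 LTR groups (HERV-K (HML-2), HERV-H, HERV9/LTR12, HERV-W, HERV-E/LTR2, HERV-I/LTR10, MER41, MER4/MER61, THE1/MST, MLT1 and MLT2/HERV-L), written down before the data were examined, was set against 10000 random groups of copies drawn from the same 10 bins of expression, where at least 5 copies were listed. The copies of the group itself could be drawn too, so the random groups for a large group such as MLT1 hold many of its own copies.

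Over the 4 lines, copies were tested in limma 3.58.1 with a trend and a term for the line, and groups in camera with a preset correlation of 0.01. The same limma model with a term for the siRNA was fitted to the 49 copies of both siRNA tables, 8 libraries per treatment. Genes with a mean count of at least 10 (85 of 87) were tested with edgeR 4.0.16 quasi-likelihood on the counts with the depth implied by RPKM, with terms for treatment and siRNA. DESeq2 1.42.0, limma-voom and TMM factors were alternatives. All p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The 6 gene groups were interferon-stimulated genes, sensors, interferon signalling, antigen presentation, restriction factors and interferons. Divergence was related to 7 rates and to 18 median log2 changes per subfamily by Spearman and Pearson correlation with 100000 permutations, and the 25 relations were adjusted together, a family larger than the one planned. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

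The copies and genes named were fixed by a rule. For the test over lines, these were the 5 copies with the smallest p. For comparisons of 1 column or library, they came from the 3 largest rises and 2 largest falls among copies at or above the median mean of the table. For genes, they were the 10 largest rises and up to 4 members per group with the largest mean. HERVK-int, LTR5_Hs, LTR7, HERVH-int, LTR12C, HERV9-int and THE1B were always named. The siRNA targets were to be named too but are not among the 87 genes. Other names, such as LTR12D, LTR10A and MER11C among LTRs and PTPRC, SPON2, MYD88, IFIT5 and FAM111A among genes, were chosen after their values were seen. A fold against 0 reads was set as a bound against a floor of 3 reads.

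Planned tests within HL60, MCF7 and HepG2, of differences between lines and with a replicate block could not be run, because each line and treatment has 1 column and the tables do not say whether it pools the replicates of the labels. Planned tests of viral defence genes over cell lines could not be run, because the gene table holds the siRNA libraries. On simulated data, limma recovered 200 of 200 copies changed by a log2 of 3 with 8 false calls, edgeR recovered 30 of 30 genes changed 2-fold with 1 false call, and 6% of 200 simulated relations without effect had p under 0.05. The limma recovery does not show the power of the real fit over the lines. There, 0 of 6449 copies passed (smallest limma adjusted p 0.323), not even an MLT1C on chromosome 2 that was higher by a log2 of at least 2.59 in every line.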

Results

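Total RNA was sequenced in 30 libraries of 4 human cancer cell lines: HCT116 from a colorectal carcinoma, HL60 from an acute myeloid leukaemia, MCF7 from a breast carcinoma and HepG2 from a liver carcinoma. The DNA methyltransferase inhibitor 5-aza-CdR (decitabine) was compared with phosphate-buffered saline (PBS), at 300 nM for 24 h in HCT116 and HL60 and at 100 nM for 72 h in MCF7 and HepG2, with harvest on day 5. The 14 libraries without siRNA were 1 per arm in HCT116 and, by the labels, 2 per arm in each other line. The 16 siRNA libraries were all of HCT116, 8 with PBS and 8 with 5-aza-CdR, and in each set 7 siRNAs had a target while siNon-target was the control. The targets were SETDB1, SETDB2, SUV39H1, SUV39H2 and EHMT2 (G9a), which are related to or act as histone H3 lysine 9 methyltransferases, EZH2, the histone H3 lysine 27 methyltransferase of Polycomb, and TRIM28, a corepressor that recruits SETDB1. The measured items were single genomic copies of long terminal repeats (LTRs) and internal parts of endogenous retroviruses on the hg19 genome, and 87 genes of the viral defence response. Sequencing depth implied by the cell-line table was 57.3, 49.2, 49.02 and 53.7 M reads (M, 1000 × 1000) with PBS in HCT116, HL60, MCF7 and HepG2, and 55.8, 50.4, 48.8 and 23.6 M with 5-aza-CdR. The siRNA libraries held 32.8 to 59.96 M reads by the LTR tables and 32.2 to 77.2 M by the gene table. The cell-line table has 1 column per line and treatment, so its differences, like each siRNA against siNon-target, have no replicate check. Intervals beside folds are exact 95% intervals that cover counting error only.

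The first comparison asked which LTRs were transcribed at a higher level after DNA demethylation in each line. In HCT116, copies of the HERV9/LTR12 group, primate endogenous retroviruses whose LTRs can act as promoters, stood out: 172 of 256 copies were at least 2-fold higher with 5-aza-CdR, with a median log2 difference of 1.76. Within that group, LTR12C was 2-fold higher at 116 of 161 copies (72.0%, median log2 2.07) and HERV9-int at 26 of 33 copies (78.8%, median log2 2.65). HepG2 had 85 of 256 HERV9/LTR12 copies 2-fold higher (median log2 0.53), including 57 LTR12C and 16 HERV9-int copies. The same group was 2-fold higher at 28 copies in HL60 (median log2 0.16) and at 26 copies in MCF7 (median log2 0.14), and in HL60 its median lay below the median of all copies. Against 10000 random sets of copies of like expression, the HERV9/LTR12 median was at percentile 100 in HCT116, HepG2 and MCF7 and at 11.2 in HL60. The HL60 rank was not stable, at percentile 76.2 with a pseudocount of 0.01, 74.05 without the filter and 92.65 with scaled counts in place of RPKM.

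Other groups differed by line. HERV-H, whose LTR7 promoter is active in pluripotent stem cells, was 2-fold higher at 39 of 109 copies in HCT116 (median log2 0.70, percentile 99.99), of which 24 were HERVH-int. HERV-I/LTR10 followed with 34 of 101 copies (percentile 97.2) and HERV-W with 13 of 44, whose percentile of 97.53 was not stable (83.96 with a pseudocount of 0.01, 93.1 without the filter and 86.7 with scaled counts). In HL60, MER4/MER61 was 2-fold higher at 61 of 240 copies (median log2 0.46, percentile 98.6, or 96.8 with a pseudocount of 1), whereas MLT1 (393 of 1632 copies, percentile 0.22) and HERV-I/LTR10 (18 of 101 copies, percentile 0.98, or 3.02 with scaled counts) had medians below most matched sets. MLT1, an old group shared by placental mammals, was 2-fold higher at 311 of 1632 copies in HepG2, with its median log2 of 0 at percentile 0. Its share of copies 2-fold higher was nonetheless 24.1% in HL60 and 19.1% in HepG2, against 21.8% and 18.5% of all copies. HERV-K (HML-2), the youngest human group, was 2-fold higher at 11, 16, 3 and 5 of 71 copies in HCT116, HL60, MCF7 and HepG2, and its medians stayed inside the range of matched sets. Of its members, LTR5_Hs was 2-fold higher at 4 of 21 copies in HCT116 and at 0 in HepG2, and HERVK-int at 1 of 13 in HCT116 and 3 in HepG2. LTR7 was 2-fold higher at 4 of 16 copies in HCT116 and THE1B at 30 of 125. HERV-E/LTR2 (8, 14, 4 and 10 of 49 copies in the same order of lines), MER41 (32, 19, 9 and 23 of 110), THE1/MST (156, 169, 29 and 138 of 801) and MLT2/HERV-L (82, 80, 15 and 70 of 410) had medians inside the range of matched sets in each line.

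Single copies reached larger differences. In HL60, an LTR7C on chromosome 6 (68590889 to 68591329) was 244-fold higher with 5-aza-CdR (interval 104 to 752), at 1189 against 5 reads. The adjoining HERVH-int (68591330 to 68598554) was 159-fold higher (129 to 198), at 13634 against 88 reads, and a further HERVH-int piece (68598640 to 68598779) was 110-fold higher (42.5 to 404). In HCT116, an LTR9B on chromosome 6 (161729870 to 161729960) was at least 39.4-fold higher and an MLT1C on chromosome 13 (111482303 to 111482377) at least 33.5-fold higher, each bound set against a floor of 3 reads because PBS gave 0. An MLT1J2 on chromosome 13 (111477343 to 111477461) had 196 reads against 1 in HCT116, a ratio of 214 (38.02 to 8508). In MCF7, LTR12C copies on chromosome 10 (9225130 to 9226520) and chromosome 3 (33487954 to 33488518) were 86.1-fold (36.6 to 267) and at least 18.9-fold higher, and a MER21B on chromosome 21 (9828352 to 9828494) was at least 4.72-fold higher. In HepG2, MLT1G3 and MLT1F2 copies on chromosome 11 (2228661 to 2228950 and 2231432 to 2231555) were 114-fold (51.6 to 312) and 84.2-fold (40.2 to 212) higher, and a MER41B on chromosome 6 (64102536 to 64102590) at least 8.33-fold. Lower with 5-aza-CdR were, in HL60, an LTR6A on chromosome 9 (79013621 to 79013650; 6 against 286 reads, ratio 0.0215) and a MER51-int on chromosome 6 (42927279 to 42927377; at least 12.4-fold lower). In HCT116 an LTR78 on chromosome 6 (46965502 to 46965604) had a ratio of 0.0795, and a MER31B on chromosome 21 (45582757 to 45582864) was at least 1.83-fold lower there and at least 3.47-fold lower in HepG2. In MCF7 a LOR1b on chromosome 1 (148602647 to 148602869) had 1 read against 23 (ratio 0.0439, interval 0.00107 to 0.271) and an LTR22 on chromosome 19 (562158 to 562235) had 0 against 4 reads, with an interval of the ratio up to 1.53 that includes no change, and in HepG2 the same LTR6A was at least 1.60-fold lower.

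Of 6449 copies with a mean RPKM of at least 0.1, 1494 were 2-fold higher and 373 lower in HCT116, 1409 and 101 in HL60, 370 and 241 in MCF7, and 1196 and 266 in HepG2. Counting error alone gave 96.1, 95.9, 135 and 189 copies 2-fold higher in simulated libraries, and 104, 97.52, 135 and 314 lower on average, and at most 130 lower in HL60 and 364 in HepG2. On the authors' scale, the numbers of lower copies in these 2 lines thus did not exceed the range of counting error, although single copies such as the LTR6A in HL60 were lower beyond it. For HL60 this depends on the scaling: with each column centred on its median, 208 copies were lower in HL60, above that range, and 340 in HepG2, still within it. The authors' deposited table, which gives folds only where a scaled count reaches 20, held 1639, 1293, 157 and 949 copies at 2-fold or more and 436, 66, 109 and 127 at 0.5 or less. The median log2 difference of all copies was 0.26, 0.29, 0 and 0.11 in HCT116, HL60, MCF7 and HepG2, and with each column centred on its median the copies higher and lower were 1142 and 643 in HCT116 and 889 and 208 in HL60. With a pseudocount of 1 RPKM in place of 0.1 the copies 2-fold higher were 330, 215, 29 and 157 in the order given.

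**Figure D1:**
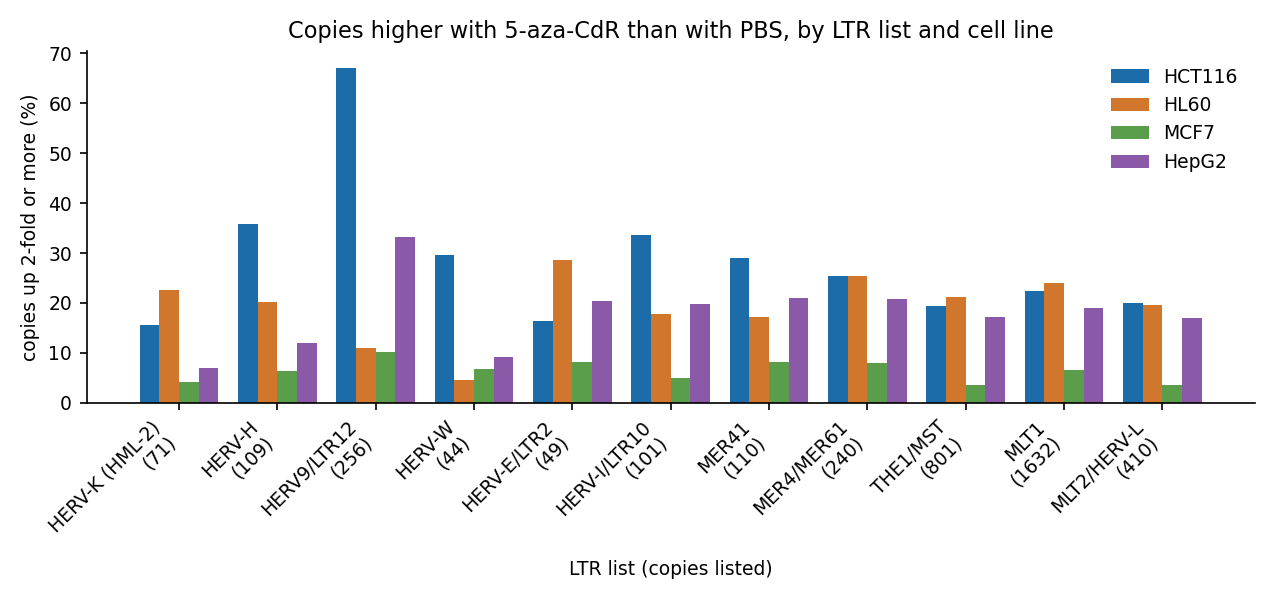
Percentage of copies at least 2-fold higher with 5-aza-CdR than with PBS in each of 11 LTR groups, by cell line (1 column per line and treatment, no error bars). HERV9/LTR12 reached 67.2% in HCT116 and 33.2% in HepG2, against 10.9% in HL60 and 10.2% in MCF7.

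The second comparison asked which copies responded alike over the 4 lines, with the lines as the replicates. The copies with the smallest p were a MER4E1 on chromosome 12 (31954925 to 31955047), higher by a log2 of 3.04 ± 0.34 (SE, 4 lines), and an MLT1C on chromosome 2 (242486123 to 242486533), higher by 4.48 ± 0.50. An LTR73 on chromosome 3 (195436081 to 195436315) was higher by 1.64, a MER66B on chromosome 5 (133813265 to 133813678) by 2.36 and an MLT1M on chromosome 7 (77159362 to 77159571) by 3.43, and all 5 copies were higher in 4 of 4 lines. Their limma Benjamini-Hochberg adjusted p ran from 0.323 to 0.610. As a group, HERV9/LTR12 was higher (median log2 0.77, limma camera adjusted p = 2.1e-08 with a preset correlation of 0.01), with adjusted p = 0.927 with an estimated correlation and an adjusted p of 0.116 in fry, which asks whether the copies move on balance and not whether they exceed others. The other 10 LTR groups did not pass camera. Of 6449 copies, 0 passed in limma, with 473 higher and 22 lower at an unadjusted p under 0.05, while edgeR on recovered reads called 293 higher and 1 lower. Centring each column on its median left 0 copies past the threshold, with 125 higher and 410 lower unadjusted. Direction was shared by all 4 lines at 660 copies that were higher and 60 that were lower. Directions drawn at random would agree in all 4 lines at 12.5% of copies if every copy had a direction in every line. The median log2 difference in MCF7 was exactly 0, and a copy at 0 cannot agree. The 660 and 60 copies can therefore not be judged against that share. The median log2 change of all copies was 0.29.

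The third comparison asked which LTRs depend on each histone methylation factor while DNA methylation is intact. With PBS, siSETDB1 had the most copies at least 2-fold above siNon-target, 327 of 791 (median log2 0.92), among them 7 of 9 HERV-I/LTR10 copies (median 1.85, percentile 99.98), 19 of 31 MLT2/HERV-L copies (median 1.11, percentile 99.2, but 84.3 with a pseudocount of 1 and 96.6 against the median of the 8 libraries) and 13 of 24 THE1B copies. With siSUV39H1, 208 copies were 2-fold higher (median 0.63), including 17 of 37 HERV9/LTR12 copies (median 0.90, percentile 99.7), of which 13 were LTR12C, and 6 of 7 HERV-H copies (median 1.17, percentile 98.7), of which 3 were LTR7. The MLT1 and MLT2/HERV-L medians with siSUV39H1 were below most matched sets (percentiles 0.435 and 1.95). Against the median of the 8 libraries they were at 2.78 and 14.1, and MLT1 was at 3.10 with a pseudocount of 1. With siEHMT2, 182 copies were 2-fold higher, of which 66 were MLT1 (percentile 99.97), and with siTRIM28 154 copies, while 0 of 7 HERV-H copies were (median -0.06, percentile 1.14). The counts were lower with siSETDB2 (74 copies), siSUV39H2 (72 copies) and siEZH2 (65 copies). With the library sizes of the gene table siEZH2 had 184 copies higher, and siSUV39H2 turned to 21 higher and 50 lower (median from 0.16 to -0.22). Among groups, HERV9/LTR12 was 2-fold higher at 4 of 37 copies for siSETDB2 (percentile 99.1, or 92.6 with a pseudocount of 1) and HERV-I/LTR10 at 4 of 9 for siSUV39H2 (percentile 98.7, or 97.3 against the median of the 8 libraries). Copies 2-fold lower numbered 3 to 24 per siRNA. With PBS as with 5-aza-CdR, only copies with a fold of at least 2 for some siRNA are listed, so a copy that was only lowered is absent. The shares of listed copies, their medians and the few lower copies therefore cannot weigh rises against falls.

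Named copies with PBS included an LTR12D on chromosome 19 (8451280 to 8451985), 9.02-fold higher with siSUV39H1 (6.70 to 12.4; 425 against 49 reads), and next to it an LTR54 (8452002 to 8452262), 8.57-fold higher (5.43 to 14.2) with siSUV39H1 and 3.92-fold higher (2.39 to 6.68) with siSETDB2. A further LTR12D there (8444045 to 8444798) was 7.90-fold higher (5.19 to 12.5) with siSUV39H1. With siSETDB1, an MSTB1 and a MER51D on chromosome 9 (69809192 to 69809324 and 69864316 to 69864367) were 12.7-fold (4.06 to 64.2) and 11.2-fold (2.77 to 97.5) higher, and a MamRep1527 on chromosome 19 (1542669 to 1542795) 12.1-fold (3.03 to 105). An MLT1B on chromosome 17 (19092260 to 19092331) was 8.55-fold higher (4.55 to 17.7) with siSUV39H2, an MLT1K on chromosome 5 (82235474 to 82235651) 5.00-fold (2.47 to 11.2) with siEHMT2, and an MLT1B on chromosome 14 (54623880 to 54624215) 4.35-fold (1.98 to 10.9) with siTRIM28. An MLT1C on chromosome 2 (217083800 to 217083964) was 4.39-fold higher with siSETDB2 and 4.05-fold with siSUV39H2, and an MLT1D on chromosome 7 (6011680 to 6011786) 3.68-fold with siEZH2. Lower copies included an MLT1B on chromosome 17 (18966159 to 18966230), with a ratio of 0.202 (0.0601 to 0.544) under siSETDB1, and an MLT1E3 on chromosome 12 (66212560 to 66213014), with 2 reads against 18 and a ratio of 0.117 (0.0132 to 0.490) under siSUV39H2. An MLT1K on chromosome 4 (178650970 to 178651177) was above siNon-target with siSETDB2, siEZH2, siTRIM28 and siEHMT2 (4.22 to 5.36-fold, 4 reads in siNon-target), and the siSETDB2 difference turned to a log2 of -0.06 against the median of the 8 libraries.

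The fourth comparison asked the same with DNA methylation already depleted. With 5-aza-CdR, siSETDB1 again had the most copies 2-fold above siNon-target, 365 of 1032 (median log2 0.83), with HERV9/LTR12 at 67 of 166 copies (median 0.92, percentile 100), made up mainly of 37 LTR12C, 12 LTR12D and 11 LTR12 copies, and with 14 of 22 THE1B copies. HERV-H did not share in it, at 2 of 15 copies (median 0.19, percentile 0.035), and MLT1 was at 89 of 251 copies with a low median for its expression (percentile 0.94, or 7.88 with a pseudocount of 1). With siEHMT2, 216 copies were 2-fold higher, with HERV9/LTR12 at 35 of 166 (median 0.71, percentile 99.99), and MLT1 and HERV-K (HML-2) at percentiles 1.74 and 1.62. With siEZH2, siSUV39H2, siSETDB2, siSUV39H1 and siTRIM28, 256, 227, 198, 171 and 133 copies were 2-fold higher, and with the library sizes of the gene table siSETDB2 had 95. Among these, HERV-I/LTR10 was high with siSETDB2 (6 of 11 copies, percentile 99.6, but 97.1 with a pseudocount of 0.01 and 95.5 against the median of the 8 libraries), HERV9/LTR12 low with siSUV39H2 (6 of 166, percentile 0.08), and HERV-H low with siEZH2 (2 of 15, percentile 0.855). With siTRIM28, HERV9/LTR12 was 2-fold higher at 10 of 166 copies (6.02%, against 12.9% of all copies), and its median of 0.38 was high only for its expression (percentile 99.4, but 96.6 with a pseudocount of 1 and 89.4 against the median of the 8 libraries), near the 0.36 of all copies. Over both treatments, 20 of 126 group and siRNA combinations lay in the lowest or highest 2.5% of matched sets. Of these, 11 left that range under at least 1 other setting. Among them were, with 5-aza-CdR and against the median of the 8 libraries, HERV-H with siEZH2 (percentile 25.1) and MLT1 and HERV-K (HML-2) with siEHMT2 (52.2 and 5.57). HERV-W and HERV-E/LTR2, with fewer than 5 copies in either table, were not ranked. No percentile was adjusted for the number of groups.

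Named copies with 5-aza-CdR included a THE1C on chromosome 1 (79112099 to 79112474), which was 13.5-fold higher with siEZH2 (4.99 to 51.01), 12.7-fold with siEHMT2 (4.70 to 48.3) and 11.6-fold with siSUV39H1 (4.26 to 44.2), and lies 269 bp from IFI44L, an interferon-stimulated gene. The THE1C further along (79114003 to 79114290) was 9.51-fold, 8.54-fold and 6.31-fold higher with the same siRNAs, with 5 reads under siNon-target. A MER89 on chromosome 12 (121457778 to 121457871), 223 bp from the interferon-stimulated OASL, had 28 reads with siEZH2 against 2 (ratio 12.6, interval 3.17 to 109). An LTR10F on chromosome 6 (66974251 to 66974750) was 11.4-fold higher with siSETDB1 (4.25 to 43.3) and 10.7-fold with siSUV39H2 (3.91 to 40.8), and an LTR40a on chromosome 4 (189311732 to 189311917) 10.3-fold with siSETDB1 (3.27 to 51.8). An LTR78 on chromosome 8 (125174776 to 125175009) had 13 reads with siTRIM28 against 2 (ratio 8.92, interval 2.02 to 81.4), and an LTR10F on chromosome 5 (115266158 to 115266367) was 6.25-fold higher with siSETDB2 (2.17 to 24.6). Lower copies included an LTR8 on chromosome X (120533730 to 120533998) with siTRIM28 (0 against 8 reads, at least 1.94-fold lower) and an MLT2B1 on chromosome 12 (113411389 to 113411898) with siSETDB1, whose ratio of 0.657 had an interval from 0.381 to 1.13.

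Copies raised in many siRNA libraries at once shared 1 control library. In the PBS table siNon-target was the lowest of 8 libraries at 231 of 791 copies (29.2%), and in the 5-aza-CdR table at 463 of 1033 (44.8%), where counting error gave 12.4% and 12.96%. With 3 or more siRNAs, 113 and 206 copies were 2-fold higher, against 11.6 and 17.9 in simulations that shared the control, and 3 and 14 copies were higher with all 7. Both tables list only copies in which some fold reached 2 at a scaled count of 20, which raises these counts, and the simulations do not allow for that choice. Centred on the median of each library, the copies higher and lower with PBS were 36 and 30 for siSETDB2, 46 and 36 for siSUV39H2, 30 and 35 for siEZH2, 25 and 43 for siTRIM28, 34 and 34 for siEHMT2, 38 and 48 for siSETDB1, and 38 and 42 for siSUV39H1. With 5-aza-CdR the centred counts were 29 and 37, 30 and 35, 43 and 33, 42 and 60, 26 and 20, 30 and 60, and 51 and 31 in the same order. Against the median of the 8 libraries in place of siNon-target, 4, 5, 6, 35, 53, 150 and 84 copies were higher with PBS and 28, 38, 25, 14, 9, 3 and 10 lower, and 17, 21, 28, 16, 22, 90 and 17 higher with 5-aza-CdR and 12, 9, 3, 68, 6, 8 and 10 lower. With the library sizes of the gene table, siSUV39H2 with PBS had 21 copies higher and 50 lower and siEZH2 with PBS 184 higher and 3 lower, more than the 175 higher of siTRIM28. A pseudocount of 1 RPKM left 4 to 61 copies higher per siRNA with PBS and 11 to 30 with 5-aza-CdR.

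**Figure D2:**
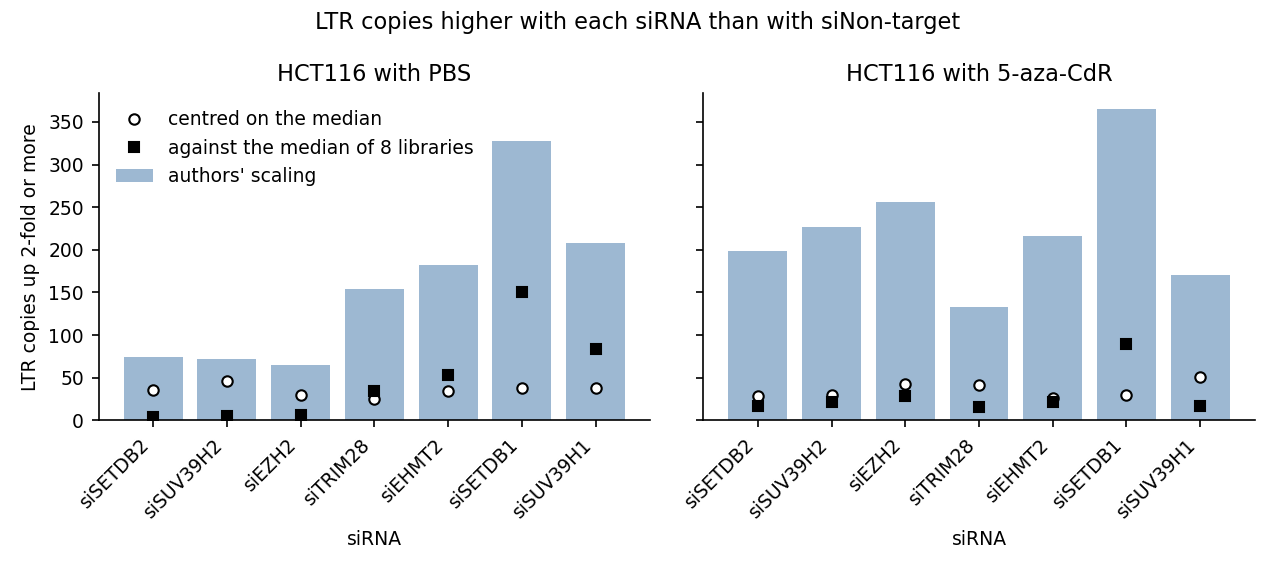
Number of LTR copies at least 2-fold higher with each siRNA than with siNon-target in HCT116 treated with PBS or 5-aza-CdR (bars, 1 library each), after centring each library on its median (circles) and against the median of 8 libraries (squares). siSETDB1 had the most copies in both sets, 327 and 365, and centring, which by construction removes a shift of all copies, left 38 and 30 of them higher.

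Copies that were 2-fold higher with an siRNA could be compared with the response of HCT116 to 5-aza-CdR alone. With PBS, 34 of 81 copies 2-fold higher with siSUV39H1 and present in the cell-line table (41.98%) were also 2-fold higher with 5-aza-CdR alone, against 2 of 33 (6.06%) for siTRIM28. For any siRNA with PBS this held for 50 of 195 copies (25.6%), and for 12 of the 50 listed copies that no siRNA raised 2-fold. On top of 5-aza-CdR it held for 137 of 173 copies (79.2%) and also for 52 of 66 copies that no siRNA raised (78.8%). The high share there thus marks the copies that table lists, which had to reach a scaled count of 20 in a treated library, and not those the siRNAs raised. The siRNA targets were not among the 87 genes, so the size of each knockdown was not checked.

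The fifth comparison asked which LTRs listed in both siRNA tables changed with 5-aza-CdR over 8 siRNA backgrounds. A MER66B on chromosome 19 (50603155 to 50603226) rose from an RPKM of 4.25 ± 3.55 to 33.97 ± 8.71 (SD, 8 libraries each), a log2 change of 3.35 ± 0.36 (SE) seen in 8 of 8 pairs (limma adjusted p = 2.18e-07). LTR12 copies on chromosome 17 (30098354 to 30099147 and 30089058 to 30089881) rose by 2.56 ± 0.29 and 2.17 ± 0.27 in 8 of 8 pairs (limma adjusted p = 2.48e-07 and 9.34e-07). A MER4A on chromosome 22 (32699065 to 32699516) rose by 1.76 and an MLT1N2 on chromosome 12 (76024213 to 76024473) by 1.70, each in 8 of 8 pairs. An MLT1C on chromosome 20 (6050887 to 6051167) fell by 0.62 ± 0.21 on the log2 scale (limma adjusted p = 0.0167; higher in 2 of 8 pairs). Of the 49 copies, 27 rose and 1 fell (median log2 0.62), and with each library centred on its median 12 rose and 6 fell. The lower copy was not called without the siSETDB1 pair or without the siTRIM28 pair. Averaged over PBS and 5-aza-CdR, siSETDB1 raised 15 of the 49 copies in limma, led by a MER11C (66679418 to 66680485, log2 2.11), an LTR10A (66699836 to 66700354, log2 2.09), an LTR70 (69824020 to 69825392, log2 2.07) and an MLT2A1 (42756640 to 42757022, log2 2.03), all on chromosome 9, with adjusted p from 0.00274 to 0.00548. After centring, siSETDB1 raised 0. The 49 copies are listed because some siRNA put them at least 2-fold above siNon-target in each treatment, in the same libraries. The p-values of the siRNAs are therefore not independent of that choice and do not stand as evidence of a rise. Limma called 0 copies for each other siRNA, with 5 at an unadjusted p under 0.05 for siEHMT2, 9 for siEZH2, 5 for siSETDB2, 11 higher and 1 lower for siSUV39H1, 8 for siSUV39H2 and 7 for siTRIM28, and with a pseudocount of 1 it called 1 for siSUV39H1.

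The sixth comparison asked how the viral defence genes of HCT116 responded to 5-aza-CdR over the same 8 backgrounds. OAS1, which makes the activator of RNase L, had 0 reads in all 8 PBS libraries and was at least 951-fold higher, MX2, a restriction factor of HIV, at least 523-fold, and the potassium channel gene KCNJ8 at least 352-fold, against a floor of 3 reads over the group. XAF1, a pro-apoptotic gene, rose by a log2 of 8.01 ± 0.41 (SE, 8 pairs; edgeR adjusted p = 1.60e-09), IFI44L by 7.87 ± 0.39 and GBP2, a guanylate-binding protein, by 7.10 ± 0.20 (edgeR adjusted p = 2.17e-11). IFI27 (6.20), IFI44 (6.05), OAS2 (5.82) and RSAD2 (5.78), which encodes viperin, followed, all higher in 8 of 8 pairs. In RPKM, IFI6 went from 1.83 ± 0.59 to 75.6 ± 57.6 and ISG15, a ubiquitin-like modifier, from 11.5 ± 1.066 to 89.99 ± 52.8 (SD, 8 libraries each). Of 85 genes tested, 84 rose and 0 fell in edgeR, with 0 lower at an unadjusted p under 0.05, and 84 rose and 0 fell in both limma-voom and DESeq2. The median log2 change was 2.07, and 81 genes were higher in all 8 pairs, while SPON2 and MYD88 were higher in 7 and IFIT5 in 6. SAMHD1, a restriction factor that lowers dNTP pools, did not pass (log2 0.19 ± 0.11, adjusted p = 0.111, higher in 6 of 8 pairs).

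By group, 28 of 28 interferon-stimulated genes rose (median log2 4.26), with OAS3 at 2.06, SP100 at 1.58, IFITM3 at 2.43 and ISG15 at 2.76. All 4 sensors of foreign nucleic acid rose (median 3.30): IFIH1 (MDA5) by 3.61, DHX58 by 3.59, DDX58 (RIG-I) by 3.02 and the double-stranded RNA kinase EIF2AK2 by 0.89. All 7 interferon signalling genes rose (median 1.78), with the transcription factors STAT1 at 1.98, STAT2 at 1.63 and IRF1 at 1.59 and the kinase JAK1 at 0.40. All 8 antigen presentation genes rose (median 1.76), with the class I genes HLA-B at 2.04, HLA-E at 1.48, HLA-A at 1.37 and HLA-C at 1.18. Of 8 restriction factors 7 rose (median 1.18), with TRIM5 at 1.34, the zinc-finger antiviral protein gene ZC3HAV1 at 1.02 and the RNA editor ADAR at 0.64. Both interferon genes rose, IFNL2 by 5.36 and IFNK by 1.47, as did PTPRC (CD45, a leukocyte marker that HL60 expresses) by 5.65. Adjusted over the list alone, the counts were 28, 4, 7, 8, 7 and 2 in the order given, and each group mean was higher in 8 of 8 pairs (exact sign-flip p = 0.00781, the smallest possible). The authors appear to have chosen the 87 genes for their response in these libraries, so these counts are not independent evidence of the direction. No group stood out from the other genes in limma camera (smallest adjusted p = 0.202, and 0.997 with an estimated correlation). Trimmed mean (TMM) factors, which centre the 87 genes, moved the median log2 change by -1.90, called 41 genes higher and 33 lower, and turned the direction of SP100, EIF2AK2, STAT2, IRF1, JAK1, HLA-E, HLA-A, HLA-C, TRIM5, ZC3HAV1, ADAR, SAMHD1 and IFNK. A downward shift of all genes of that size must do this to the smaller rises. The library sizes of the LTR tables moved the median by -0.12 and left 0 of 85 genes below 0. With them edgeR called 80 genes higher, among them 27 of 28 interferon-stimulated and 6 of 7 interferon signalling genes.

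The seventh comparison asked which siRNAs changed the viral defence genes. On top of 5-aza-CdR, the median interferon-stimulated gene was 3.54-fold above siNon-target with siEHMT2, 3.16-fold with siEZH2 and 2.80-fold with siSUV39H1, against 1.63-fold with siSETDB2, 1.19-fold with siTRIM28, 1.19-fold with siSUV39H2 and 0.898-fold with siSETDB1. With PBS the same medians were 0.972 to 1.13-fold. These folds were taken with 0.1 added to each RPKM. That holds the ratio near 1 for genes almost silent with PBS, such as OAS1 and MX2 (mean RPKM 0), RSAD2 (0.003) and IFI44L (0.005). The PBS medians are therefore partly set by the added 0.1 and cannot show that these genes did not respond. The median RPKM of these 28 genes was 10.7 with siEZH2, 9.97 with siEHMT2 and 8.72 with siSUV39H1 on top of 5-aza-CdR, 3.09 with siNon-target, and 0.202 to 0.451 over the 8 PBS libraries. IFI6 was 5.66-fold higher with siEHMT2 (5.31 to 6.04), 4.51-fold with siEZH2 (4.23 to 4.82) and 3.82-fold with siSUV39H1 (3.58 to 4.08) under 5-aza-CdR. With PBS, BST2 (tetherin) was 4.55-fold higher with siEHMT2 (2.29 to 9.86), and EGR1, an early response transcription factor, was 2.66-fold higher with siSETDB2 (2.54 to 2.78) and 2.58-fold with siSUV39H2 (2.47 to 2.69). DDIT4, an inhibitor of mTORC1, was below siNon-target with siEHMT2 (ratio 0.582, interval 0.519 to 0.652) and siSETDB1 (ratio 0.594, interval 0.535 to 0.660) under PBS.

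In edgeR, 1 effect per siRNA was fitted to PBS and 5-aza-CdR together. By that fit siEHMT2 raised 20 of 85 genes, siEZH2 16 and siSUV39H1 6, and edgeR called none lower for any siRNA. With 0.1 added to each RPKM, 2, 5 and 2 genes were 2-fold above siNon-target under PBS alone in the same order, against 33, 32 and 27 under 5-aza-CdR alone. The added 0.1 hinders genes almost silent with PBS from reaching 2-fold there, so the gap between these counts is partly set by it. The calls therefore do not show a rise in both treatments. Limma-voom called 32 higher and 1 lower for siEHMT2, 32 and 1 for siEZH2 and 15 and 0 for siSUV39H1. DESeq2 called 25 and 1, 21 and 1, and 10 and 1. Of the interferon-stimulated genes, 14, 9 and 5 were among those that edgeR called: IFI44L rose by 3.36 with siEHMT2 (edgeR adjusted p = 0.00893), 3.35 with siEZH2 (edgeR adjusted p = 0.0192) and 3.41 with siSUV39H1 (edgeR adjusted p = 0.0248). RSAD2 rose by 3.52, 3.14 and 2.74 and OAS1 by 2.99, 3.14 and 2.57 in the same order. HLA-B rose by 0.86 with siEHMT2 and 0.85 with siEZH2, IFNL2 by 3.33 and 2.69 with the same siRNAs, and FAM111A by 1.13 with siEZH2 and 0.99 with siSUV39H1. The 8 PBS libraries together held 12 reads of IFI44L, 5 of RSAD2, 6 of IFNL2 and 0 of OAS1, so for these 4 genes the PBS libraries held next to no value to compare. Their rise rests on 1 library with 5-aza-CdR per siRNA. For siSETDB1, siSETDB2, siSUV39H2 and siTRIM28 edgeR called 0 genes, with 4, 8, 10 and 1 at an unadjusted p under 0.05, while limma-voom called 1 for siSETDB2 and DESeq2 called 2 for siSETDB2, 5 for siSUV39H2 and 1 lower for siSETDB1. With TMM factors the genes higher and lower were 9 and 3 for siEHMT2, 3 and 1 for siEZH2, 2 and 1 for siSUV39H1 and 0 and 1 for siSETDB1. With the library sizes of the LTR tables siEHMT2, siEZH2 and siSUV39H1 raised 9, 2 and 1. Whether an siRNA acted differently with 5-aza-CdR than with PBS was not tested, with 1 library for each combination.

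**Figure D3:**
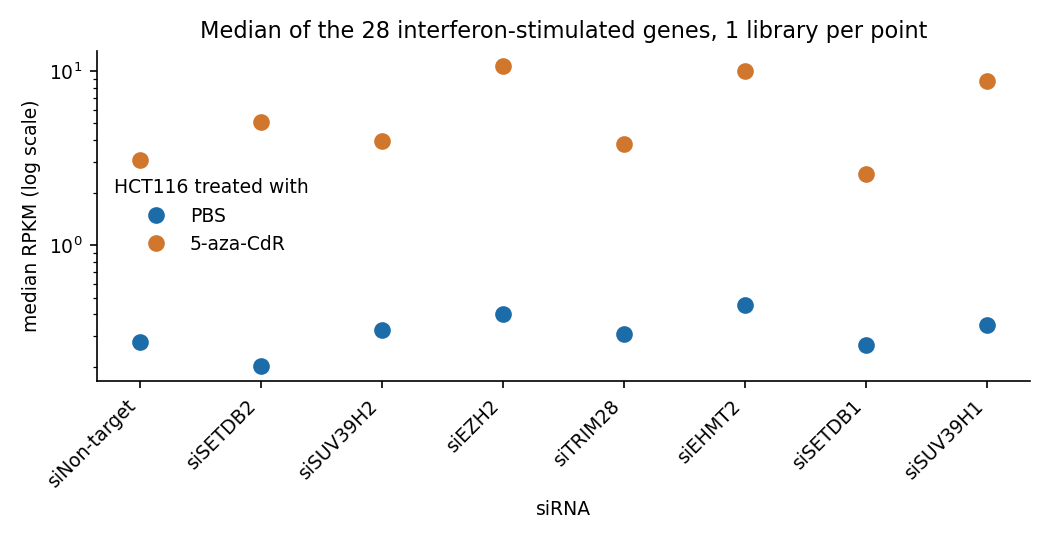
Median RPKM of 28 interferon-stimulated genes in each of 16 HCT116 libraries, by siRNA and treatment (1 point per library, log axis). All 8 libraries with 5-aza-CdR (2.58 to 10.7) lie above all 8 with PBS (0.202 to 0.451), and siEZH2, siEHMT2 and siSUV39H1 are highest.

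The eighth comparison asked whether evolutionary age, measured as the divergence of a subfamily from its consensus, went with the LTR response. In the youngest subfamilies, with divergence up to 0.1, 10.1 ± 4.4 copies per 1000 were upregulated by 5-aza-CdR in HCT116 and 7.67 ± 3.50 in HL60 (mean ± SEM, 36 subfamilies), against 1.29 ± 0.26 and 1.78 ± 0.29 in the 75 subfamilies above 0.25. HepG2 had 3.77 ± 1.60 and 0.931 ± 0.17 in the same bins and MCF7 0.667 ± 0.28 and 0.160 ± 0.06, while the rate with the knockdowns was 2.73 ± 0.70 and 1.77 ± 0.26. The medians of these bins differed less, at 1.2 and 0.8 in HCT116, 1.6 and 1.1 in HL60 and 0 in both bins in HepG2 and MCF7. With the knockdowns they were 0.55 and 1.1. Subfamilies with any upregulated copy made up 52.8% and 58.7% in HCT116, 61.1% and 61.3% in HL60, 41.7% and 45.3% in HepG2 and 22.2% and 21.3% in MCF7. Over 368 subfamilies, divergence ran from 0.048 to 0.307 and was negatively related to CpG density (Spearman rho -0.652). Of 25 relations to divergence, Pearson's r for the rates was -0.22 in HCT116 (permutation p = 1e-05, the smallest possible, adjusted p = 0.000125), -0.18 in HL60 (adjusted p = 0.000167), -0.13 in MCF7 (adjusted p = 0.0166) and -0.12 in HepG2 (adjusted p = 0.0469). Spearman's rho was weaker and did not pass for these rates, at -0.11 in HCT116 (permutation p = 0.0437, adjusted p = 0.249), -0.07 in HL60, -0.07 in MCF7 and -0.07 in HepG2 (adjusted p = 0.568 each). Whether single subfamilies with high rates carry the Pearson relation was not tested. For the median log2 change per subfamily, rho was -0.15 in HCT116 (345 subfamilies, adjusted p = 0.0622) and 0.18 with siTRIM28 and PBS (218 subfamilies, adjusted p = 0.0622; Pearson's r 0.18, adjusted p = 0.0257). These were sensitive to the settings. HCT116 passed with a pseudocount of 0.01 (rho -0.18, adjusted p = 0.0139). The relation for siTRIM28 with PBS passed with a pseudocount of 1 (rho 0.23, adjusted p = 0.00825) and against the median of the 8 libraries (rho 0.20, adjusted p = 0.0489). The rate with the knockdowns gave a rho of -0.01 and an r of -0.10 (adjusted p = 0.973 and 0.189). Subfamilies are not independent replicates.

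The rate with both treatments, called double depletion in the deposited table, had the strongest relation (rho -0.18, permutation p = 0.00048, adjusted p = 0.0120; r -0.28, adjusted p = 0.000125). That column could not be derived from the copies listed: recomputed rates equalled it for 22 of 266 subfamilies within 0.06 per 1000 or 3%, where shuffled values gave 22.6 on average. The same comparison matched for 158 of 203 subfamilies with the knockdowns. It matched for 181 of 215 in HCT116, 220 of 225 in HL60, 74 of 75 in MCF7 and 177 of 183 in HepG2. No copy number per subfamily is given, so it was derived from the deposited rates of the cell lines. The matches in the cell lines were thus largely set beforehand, and only the knockdown column is a fair comparison. LTR13A had a deposited double-depletion rate of 11.3 and a recomputed rate of 0, and LTR1 had 0 and 11.5, both chosen after their values were seen. The recomputed rates had a rho of -0.11 over 304 subfamilies (adjusted p = 0.249) and an r of -0.19 (adjusted p = 0.00269).

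**Figure D4:**
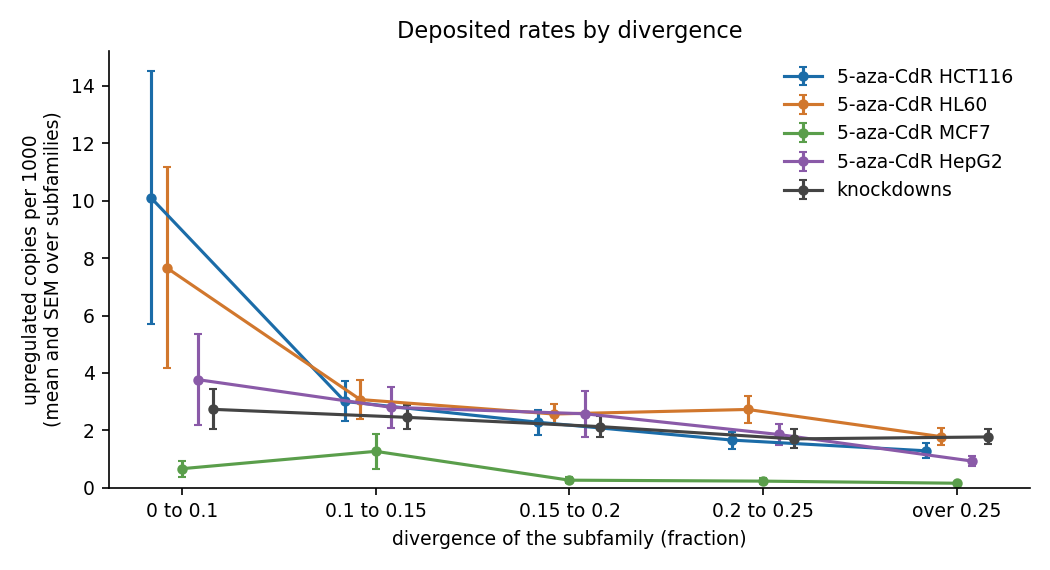
Upregulated copies per 1000 (mean ± SEM over subfamilies) in 5 bins of divergence for the deposited rates of the cell lines and of the knockdowns. The double-depletion rate is not drawn. The youngest bin (36 subfamilies) was highest in HCT116, at 10.1 per 1000, while in MCF7 the bin from 0.1 to 0.15 was highest, at 1.27.

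**Figure D5:**
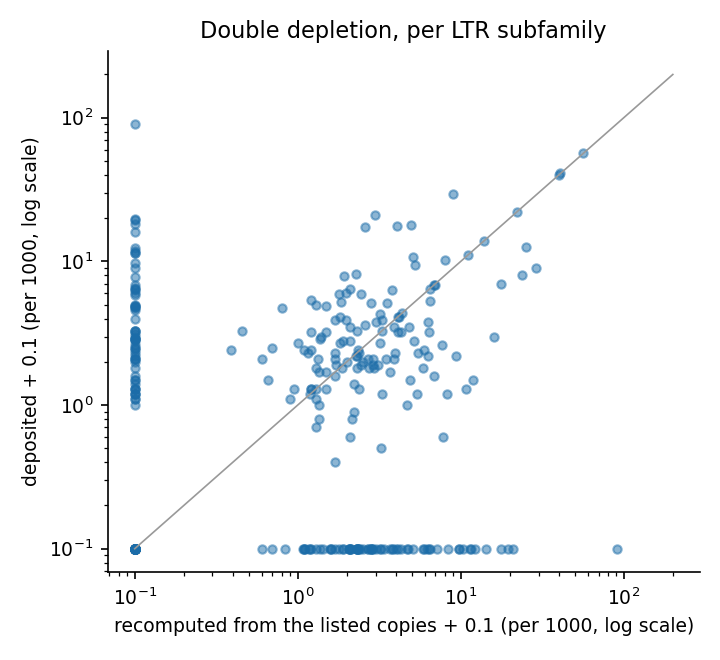
Deposited double-depletion rate of each subfamily against the rate recomputed from the copies listed with 5-aza-CdR and an siRNA, per 1000 copies. The points do not follow the line of equality, and 22 of 266 subfamilies match.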

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

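The comparison of opposite directions between lines was chosen only after the copies to name were known, and it covers those copies alone. An HERVH-int on chromosome 6 (68591330 to 68598554) moved in opposite directions in 2 lines. With 5-aza-CdR its log2 difference, with 0.1 added to each RPKM, was 6.73 in HL60 (13634 against 88 reads) and -1.30 in HepG2 (0 against 79 reads), 8.03 apart. In HCT116 it was 0.57 (28 against 3 reads) and in MCF7 -0.03 (1 against 2 reads).

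An LTR6A on chromosome 9 (79013621 to 79013650) differed by 8.25 between MCF7, at 2.48 (172 against 31 reads), and HepG2, at -5.77 (0 against 12 reads). In HL60 it was at -5.50 (6 against 286 reads), and in HCT116 it had 0 reads in both arms. A LOR1b on chromosome 1 (148602647 to 148602869) differed by 5.63 between HCT116, at 2.31 (6 against 0 reads), and MCF7, at -3.32 (1 against 23 reads). HL60 had 0 against 7 reads for it and HepG2 1 against 0. Where an arm had 0 reads, the log2 value and the gap set by it depend on the added 0.1 RPKM, and the LTR6A in HepG2 was at least 1.60-fold lower against a floor of 3 reads.

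The 3 differences were not tested, because each line has 1 column per treatment, and dose and duration also differed between HL60 and HCT116 on one side and MCF7 and HepG2 on the other. No technical or biological explanation was tested for them.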

How the results depend on the processing

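Pseudocount, filter on low values, centring, the median of 8 libraries as the control, the divergence relation in copies at or above the table's median, the estimated correlation, fry on the LTR groups, limma without trend over the lines and the 8 pairs, and leaving out each line or, for the 49 copies, each siRNA pair were chosen before the data were examined. Scaled counts, the authors' criterion, library sizes of the other tables, edgeR on recovered reads, and every alternative for the viral defence genes (TMM, limma-voom, DESeq2, no siRNA term, no filter, leaving out pairs, fry) were chosen after the files were seen. Within a cell line, no paired analysis was possible because the labels give replicate numbers 1 and 2 in HL60, MCF7 and HepG2 while the columns carry none. The fits over 4 lines and over 8 siRNA backgrounds did pair the columns, by line and by siRNA. For the same reason the replicate block, the leaving out of single libraries, the 4 libraries of a line alone, and DESeq2 or TMM on LTR counts per line were not run, nor was any alternative for viral defence genes in cell lines.

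Of 360 alternative counts, 250 stayed within 1.5 times the reported count. Of 976 group medians, 931 moved by less than their spread and 64 changed sign against their matched groups, of which 1 belonged to the 165 values of groups outside the matched range. Of 520 values of named copies in comparisons of 1 library, 461 moved by less than their counting interval and 1 turned. All 167 values of copies named from the fits kept their direction, and 161 also their side of the threshold. Of 462 values of named genes, 444 kept both, as did 46 of 59 relations to divergence and 36 of 45 group tests.

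A pseudocount of 1 RPKM, which shrinks ratios of low values, left 330 copies 2-fold higher and 53 lower in HCT116, 215 and 10 in HL60, 29 and 5 in MCF7, and 157 and 8 in HepG2. With PBS it left 10 copies higher for siSETDB2, 11 for siSUV39H2, 4 for siEZH2, 17 for siTRIM28, 25 for siEHMT2, 61 for siSETDB1 and 44 for siSUV39H1, and with 5-aza-CdR 15, 14, 18, 11, 15, 30 and 12. It gave 1 copy higher with siSUV39H1 among the 49, a rho with divergence of 0.23 for siTRIM28 with PBS (adjusted p = 0.00825), and 0.0266 for siEZH2 with 5-aza-CdR, from -0.0432. A pseudocount of 0.01 gave 599 copies lower in HCT116, 2235 higher and 225 lower in HL60, 1055 and 713 in MCF7 and 1922 and 793 in HepG2. It gave 105 copies higher for siEZH2 with PBS, and with 5-aza-CdR 346 for siSUV39H2, 207 for siTRIM28, 328 for siEHMT2 and 265 for siSUV39H1. Its rho with divergence was -0.18 in HCT116 (adjusted p = 0.0139) and -0.0167 for siSUV39H1 with PBS, from 0.00359.

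Centring each library on its median, which by construction removes a shift of all copies, gave 643 copies lower in HCT116 and 889 higher and 208 lower in HL60. The copies higher with PBS became 36 for siSETDB2, 46 for siSUV39H2, 30 for siEZH2, 25 for siTRIM28, 34 for siEHMT2, 38 for siSETDB1 and 38 for siSUV39H1, and with 5-aza-CdR 29, 30, 43, 42, 26, 30 and 51. Among the 49 copies 12 were higher and 6 lower with 5-aza-CdR and 0 higher with siSETDB1. The direction of MLT1 in camera turned (adjusted p = 0.929, from 0.822).

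Against the median of the 8 libraries, 4, 5, 6, 35, 53, 150 and 84 copies were higher with PBS and 17, 21, 28, 16, 22, 90 and 17 with 5-aza-CdR, in the same order. The MLT1K on chromosome 4 (178650970) went from 1.81 to -0.0604 for siSETDB2 with PBS, and MLT1 minus its matched groups for siEHMT2 with 5-aza-CdR from -0.07 to 0.00360. The rho with divergence was 0.20 for siTRIM28 with PBS (adjusted p = 0.0489) and -0.0199 for siSUV39H1 with PBS. That median includes the siRNA libraries, so a low siNon-target library and a rise shared by several siRNAs both lower these counts, and the cause was not tested.

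Scaled counts gave 567 copies lower in HCT116, 236 lower in HL60, 1076 higher and 708 lower in MCF7 and 564 lower in HepG2, with 1 added to each scaled count. The authors' criterion in the authors' deposited table gave 66 lower in HL60, 157 higher and 109 lower in MCF7 and 127 lower in HepG2. Library sizes of the gene table gave 21 copies higher for siSUV39H2 and 184 for siEZH2 with PBS and 95 for siSETDB2 with 5-aza-CdR. Over the 4 lines, edgeR on recovered reads called 293 copies higher and 1 lower, where limma called 0 under each alternative (smallest adjusted p 0.0526 to 0.717), including without any 1 line. Leaving out each siRNA pair gave 22 to 29 of the 49 copies higher and 0 to 1 lower, with 0 without siSETDB1 or without siTRIM28. HERV9/LTR12 over the lines had an adjusted p of 0.927 with an estimated correlation and 0.116 in fry.

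For viral defence genes, TMM factors, which centre the 87 genes by construction, called 41 higher and 33 lower with 5-aza-CdR, 9 and 3 with siEHMT2, 3 and 1 with siEZH2, 2 and 1 with siSUV39H1 and 0 and 1 with siSETDB1. Shifting all genes alike by -1.90, they moved the smaller rises below 0, which says nothing of these genes singly: HLA-A to -0.53, HLA-C to -0.72, HLA-E to -0.42, EIF2AK2 to -1.01, JAK1 to -1.50, STAT2 to -0.27, IRF1 to -0.31, SP100 to -0.32, IFNK to -0.39, ADAR to -1.26, ZC3HAV1 to -0.87, SAMHD1 to -1.71 and TRIM5 to -0.56. Library sizes of the LTR tables gave 9 genes higher with siEHMT2, 2 with siEZH2 and 1 with siSUV39H1. Limma-voom gave 32 higher and 1 lower with siEHMT2, 32 and 1 with siEZH2, 15 higher with siSUV39H1 and 1 with siSETDB2. DESeq2 gave 1 lower each with siEHMT2, siEZH2, siSETDB1 and siSUV39H1, and 10 higher with siSUV39H1, 2 with siSETDB2 and 5 with siSUV39H2. Leaving out each siRNA pair left 83 to 85 genes higher with 5-aza-CdR. In fry, which tests a shift of the group itself, adjusted p was 3.77e-08 for antigen presentation, 1.18e-06 for sensors, 2.80e-07 for signalling, 7.54e-07 for interferon-stimulated genes, 2.80e-05 for interferons and 1.21e-06 for restriction factors. The cause of the differences between tools was not tested.

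In copies at or above the table's median, rho with divergence was -0.0648 for siEHMT2 and -0.0583 for siSUV39H1 with PBS, and with 5-aza-CdR -0.0730 for siSUV39H2, 0.00170 for siEZH2, -0.0198 for siEHMT2, -0.0825 for siSETDB1 and -0.00101 for siSUV39H1, each of the opposite sign to the reported value and without passing. Depth limits the copies with few reads most: HepG2 with 5-aza-CdR had 23.6 M reads, and simulated counting error alone put 314 of its copies 2-fold lower.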

Other observations

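In the following paragraphs, the tests of splits for edgeR and for the LTR groups over the lines had their outcome written down beforehand, and the other tests of splits and the tests of the 3 patterns below were chosen only after the result was seen. Of 6449 copies, 15 were at least 2-fold higher with 5-aza-CdR in all 4 lines, 137 in 3 and 765 in 2. The 15, chosen after their values were seen, included neighbours. On chromosome 12, MER4E1 (31953677 to 31954072) was higher by a log2 of 5.37, 1.99, 2.20 and 1.71 in HCT116, HL60, MCF7 and HepG2, and LTR12C (31957612 to 31959289) by 3.31, 1.01, 1.43 and 2.32. On chromosome 3, LTR12C (33494769 to 33496479) was higher by 3.24, 1.12, 3.44 and 3.61, and MER57A-int (33496539 to 33496814) by 2.56, 1.15, 3.57 and 1.23. The others were MSTB, MER4E1, MLT1C (3 copies), LTR73, LTR49-int, MER52A, MER66B, MLT1M and MLT2B3.

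Copies 2-fold higher were shared more than independence gives by HCT116 and MCF7 (137 against 85.7), MCF7 and HepG2 (103 against 68.6) and HCT116 and HepG2 (354 against 277). HL60 shared them with HCT116 (337 against 326), MCF7 (86 against 80.8) and HepG2 (249 against 261) about as independence gives. In the top quartile of CpG density 32.6% of copies were 2-fold higher in HCT116, against 19.8% in the lowest quartile. In HL60 the same quartiles had 17.6% and 24.9%, in MCF7 6.89% and 6.01% and in HepG2 19.4% and 20.1%.

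With PBS, siSUV39H1 stood apart by its LTR12 copies, 17 of 37 at least 2-fold higher. If RNA of a library treated with 5-aza-CdR had entered this library, the 15 of these copies in the cell-line table would need a share of at least 31.6%. The 8 genes near 0 with PBS had 12 reads, against 796 in siNon-target with 5-aza-CdR, an upper bound of 2.14%, which argues against it. A library size set too low would raise all features alike. The upper quartile of 60 measured genes was 0.463 in log2, below the LTR12 median of 0.904. The genes cannot decide this, because their library sizes differ from those of the copies (59.6 and 53.6 M in siNon-target). The median of all copies was 0.629, so part of the LTR12 rise was shared by all copies, and for that part the library size remains open. That LTR12 depends on SUV39H1 with DNA methylation intact may be held as a hypothesis only, since siRNA off-target effects were not tested and there was 1 library.

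LTR copies within 10000 bp of viral defence genes were high with 5-aza-CdR and siEZH2, siEHMT2 or siSUV39H1, with 20, 12 and 12 of 24 copies 2-fold higher, against 23.4%, 20.2% and 15.8% of 1009 copies farther off. The 24 copies lie beside 17 genes, 9 of them interferon-stimulated. Over the 7 siRNAs their median correlation with the interferon-stimulated genes was 0.821, above the highest of 10000 random sets (0.321), so transcription linked to the neighbouring gene, including read-through, may account for part of the pattern. A library size set too low would raise both sets alike, which is argued against for siEZH2, where the lower quartile near the genes (1.10) exceeded the median farther off (0.612), and for siSUV39H1 (0.840 against 0.430). For siEHMT2 (0.605 against 0.606) it cannot be told apart, because the quartile and the median nearly coincide. This form of the size test was the first of 3 tried and was kept after the others were seen: a test of the near median against the highest random set left siEHMT2 open as well (0.997 against 1.06), and the share of random sets as high (0.01%, 0.04% and 0.01% for siEZH2, siEHMT2 and siSUV39H1) was tried and set aside.

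The double-depletion rates of the age table could not be derived from the copies listed. Of 64 rates of at least 5 per 1000, 9 equalled the recomputed rate of their own subfamily and 49 that of a subfamily within 10 places of the table, against 9.88 on average and at most 18 in 1000 shuffles, so rates that stand beside other subfamilies' names are a candidate explanation. This test replaced a first one without power (51 of 64 rates found anywhere in the table, where 604 of 1000 shuffles gave as many), and its window was picked after 5, 10, 20 and 40 places and minimum rates of 3, 5 and 8 had been tried, all with more matches than any of 100 shuffles. Of the rates, 31.97% make whole copies (at most 39.5% in shuffles), against 99.2% in the knockdown column. This argues against rates that count other copies of the same subfamilies. The cell-line columns had 95.2% to 99.2%, but the copy numbers were derived from those columns. No biological explanation was tested.

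For the viral defence genes, 1 of 100 splits of the 16 libraries, the real one, gave as many as 84 genes (highest other 60), and of 100 splits that part each siRNA pair again 1 (highest other 73). The genes appear to have been chosen for their response in these libraries, so the splits alone decide nothing, but 58 of the 85 genes had an edgeR p below 5e-07, the limit for a choice among 100000 genes, and all 58 were higher in 8 of 8 pairs. That limit was chosen after the values were seen, and the p-values take the 8 siRNA backgrounds as replicates of the treatment. On those terms it argues against chance for these 58 genes but does not exclude it. A batch difference between the treatments was not tested. For the 49 LTR copies, 1 of 100 splits gave as many as 28 (highest other 17), and 1 of 100 that part each pair (highest other 16). This argues against chance there, again with the siRNA backgrounds as the replicates. Over the 4 lines, 32 of 35 splits in limma gave at least the real 0 copies (highest other 1, and 3 splits could not be fitted), which any split does and which therefore decides nothing. With edgeR on recovered reads 3 of 35 splits gave as many as 294 (highest other 307), so chance cannot be excluded, while of the 8 that part each line only the real one did (highest other 154). For the LTR groups 21 of 35 splits gave at least the real 1 (highest other 4), so chance cannot be excluded for them either.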
